A study of Mus musculus with 2 samples.

How the data were processed

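Cells were sorted by the submitters from spleens on CD11b and Gr1, loaded on the 10x Genomics Chromium platform and sequenced as 3′ libraries with version 2 reagents, per the labels' protocols, which give an average of 48488 reads per cell. Per the submitters' processing notes, the reads were processed with Cell Ranger 2.1.0 on the mm10 build. The deposited files hold raw counts of unique molecular identifiers (UMIs) per gene and cell, and each library has 27998 gene rows. All values were whole and none was below 0. The lowest cell held 2752 UMIs in the wild-type and 2502 in the PyMT file, so a lower limit on cells had been set before deposit; what set it is not given in the sources used here. The files hold no cell annotation. Immunoglobulin and T cell receptor constant genes were not analysed here.

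From those counts, cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 5 PyMT cells. Both libraries were clustered together in Python 3.11.15 with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1), leaving out the genes of the suppressor, inflammatory, immediate-early, interferon and cell cycle lists. Each of the 24 clusters was named from 15 fixed marker lists by the mean scaled level of markers reaching 50 CPM in some cluster. A cluster needed a score of 0.5 and 3 detected markers for a name, was called mixed when another lineage also reached 0.5, and stayed unnamed when its 10 leading genes held more markers of another lineage. This scoring rule was set after the data were seen, as was the 1.5-fold condition for lists that go opposite ways; the markers were not. No doublets were removed in the main comparison. As an alternative, the cells that most resembled simulated doublets were left out at 0.8% per 1000 cells, which took 241 wild-type and 670 PyMT cells. Those included 15.3% of the wild-type and 88.6% of the PyMT cells of mixed cluster 8, 7.38% and 91.0% of mixed cluster 12, 17.9% and 84.9% of mixed cluster 18, and 24.0% and 39.3% of the PyMT cells of clusters 14 and 15.

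UMIs were summed per library and class and scaled to the total of that sum as CPM, with exact Poisson 95% intervals. Log2 ratios are PyMT over wild type with the exact conditional interval, and shares have exact Clopper-Pearson intervals. Intervals cover counting error only. A group at 0 UMIs was set to a floor of 3 counts in its sum, which gives a bound. Classes were compared with at least 200 cells in each library. With 1 library per group, no p-value, standard error or count of changed genes was made from cells. Resampled ranges, where given, are over list members, genes or cells of these libraries and are not replicate checks. Samples were grouped by the submitters' titles and strain labels.

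Genes are named by a rule fixed before the data were examined. Among genes with at least 100 UMIs in sum, ranked by the interval bound nearest 0, it takes the 12 highest and 12 lowest in neutrophil-like cells, 6 and 6 in the other classes and 8 and 8 over the whole library. Ribosomal and mitochondrially encoded genes, receptor segments and unnamed gene models stay out. It adds up to 4 members of each list with at least 50 UMIs and the largest ratios, and all genes of the sorting panel. S100a8 in B cell-like cells and the genes given by cluster or under other observations were chosen after their values were seen. Each of 26 gene lists is given by its median log2 ratio over members with at least 50 UMIs, by the number of members at least 1.5-fold higher or lower, and by the percentile of its median among 10000 random lists matched on expression in 20 bins, as a description of these libraries. Shares of cells with a UMI and genes per cell were also computed after each cell was thinned to 1000 UMIs, which left out no cell. Gene positions are from GENCODE release M21 on GRCm38.

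The comparison was tested on sums simulated as Poisson counts from a shared profile with 200 changed genes. The intervals assume such counts, so this checks the calculation and not variation between cells, mice or libraries. In the neutrophil-like class the direction was recovered for 90.0% of 50 genes changed 1.5-fold and for all of the 50 genes changed 4-fold, among 7716 genes, and intervals held the true value for 95.2% of 7516 unchanged genes. In the B cell-like class, the shallowest, the direction was recovered for 70.0% of 50 genes changed 1.5-fold among 4535 genes.

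The alternatives were a trimmed mean of M-values, the median of ratios, a total without the 50 most abundant genes, equal weight per cell, thinned counts, no cell filter, a filter of at least 500 genes and at most 5% mitochondrial UMIs, doublets left out, Leiden resolution 0.5, each library clustered on its own, clustering with the list genes, and list members with at least 200 or 10 UMIs. Leaving out neutrophil-like clusters under 20000 CPM of Camp, and the monocyte-like cluster with neutrophil transcripts, was added after the data were seen.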

Results

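Spleen cells carrying the surface proteins CD11b and Gr1, which mark neutrophils and many monocytes, were profiled by droplet single-cell RNA sequencing in control mice and in mice with mammary tumours. The wild-type library pooled 5 spleens of FVB/n mice, and the PyMT library pooled 3 spleens of tumour-bearing mice that express the polyoma middle T antigen. The labels call the strain of the latter only PYMT. The wild-type library held 5491 cells and 42542700 UMIs, and the PyMT library held 9155 cells and 73435307 UMIs. Each group is 1 library, so no test between conditions exists and no value has a replicate check. The 95% intervals given here cover counting error only, and every difference is between these 2 libraries. The study looks for myeloid-derived suppressor cells, neutrophil-like and monocyte-like cells that restrain T cells in cancer.

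To describe what the sort contained, cells were clustered and named from markers fixed before the data were examined. Neutrophil-like cells made up 59.1% of the wild-type cells (exact binomial interval 57.8 to 60.4%) and 57.3% of the PyMT cells (56.2 to 58.3%). Monocyte-like cells were 10.1% in wild type (9.27 to 10.9%) and 17.8% in PyMT (17.0 to 18.6%). B cell-like cells were 5.19% (4.62 to 5.81%) and 10.9% (10.2 to 11.5%), although the sort should exclude most of them. Myeloid progenitor-like cells, which carry primary granule genes such as Mpo and Elane, were 5.04% in wild type and 1.29% in PyMT, but with each library clustered on its own their share was 0.93 percentage points higher in PyMT. The neutrophil-like share was then 6.69 points lower. Clusters in which markers of another lineage also reached the score for a name were kept apart as mixed. They held 17.3% of wild-type and 8.58% of PyMT cells. The doublet shares expected from the number of cells at 0.8% per 1000 were 4.39% and 7.32%. In the largest mixed cluster, cluster 8, 15.3% of wild-type and 88.6% of PyMT cells were among those most like simulated doublets. Those shares depend on the fixed number taken per library, 241 wild-type and 670 PyMT cells. The median doublet score of cluster 8 was 0.843 in wild type and 0.922 in PyMT. The lowest scores left out were 0.8824 and 0.8627. The thresholds that set mixed clusters apart were chosen after the data were seen, and the sorting gate sets these shares in part. Depth differed by class: the median was 5227 UMIs per neutrophil-like cell in wild type and 8087.5 in PyMT, and 5384 and 7360.5 in monocyte-like cells, while it was 11402 and 7631 in mixed and 3643 and 3349 in B cell-like cells.

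**Figure D1:**
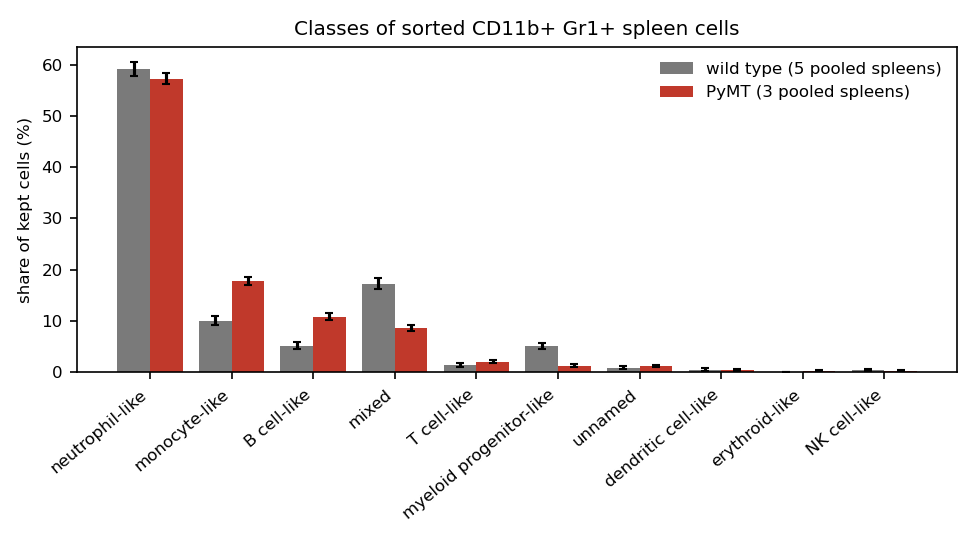
Share of kept cells (%) in each class for the wild-type library (grey) and the PyMT library (red), with exact binomial 95% intervals as error bars. Neutrophil-like cells were 59.1% and 57.3%, while monocyte-like cells were 10.1% and 17.8%.

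To ask how neutrophil-like cells differ between tumour-bearing and control spleens, UMIs were summed over 3245 wild-type and 5240 PyMT cells. Different clusters hold most of these cells in each library, clusters 1 and 6 in wild type and clusters 3, 5, 7, 9 and 10 in PyMT. Wfdc17, which encodes a small secreted whey acidic protein domain protein, was at 24.5 CPM, UMIs scaled to the total of the sum, in wild type and 5715 in PyMT, a log2 ratio of 7.86 (7.73 to 8.00). Ifitm1, an interferon-induced membrane protein gene, was at 29.5 and 3045 CPM, a log2 ratio of 6.69 (6.57 to 6.81). Socs3, which encodes a feedback inhibitor of cytokine signalling, was at 3.32 and 134 CPM, a log2 ratio of 5.33 (4.98 to 5.70). Saa3, an acute-phase gene, was at 0.205 and 39.9 CPM, and the protease inhibitor gene Stfa2 was at 17.4 and 862 CPM. Steap4, a metalloreductase gene, had 0 UMIs in wild type and 2268 in PyMT, a log2 ratio of at least 8.39 against a floor of 3 counts in the wild-type sum. Wfdc18, Cxcr1 and Ambp also had 0 wild-type UMIs, with log2 ratios of at least 6.34, 5.59 and 5.11 against the same floor. Igfbp6, Il13ra1 and Prr5l completed the 12 highest genes, with log2 ratios of 8.24, 5.34 and 5.85. A few cells carried part of the lower level. The 55 wild-type cells in clusters with at least 90% PyMT cells held 333 of the 480 wild-type UMIs of Wfdc17, 295 of 576 of Ifitm1, 157 of 341 of Stfa2 and 17 of 65 of Socs3. In the other wild-type cells Wfdc17 was at 7.68 CPM, Ifitm1 at 14.7 and Stfa2 at 9.61. Igfbp6 and Prr5l had 6 and 5 wild-type UMIs in all.

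In the other direction, Thbs1, which encodes the matrix protein thrombospondin 1, was at 184.5 CPM in wild type and 3.17 in PyMT, a log2 ratio of -5.87 (-6.12 to -5.62), and 43 of its 140 PyMT UMIs lay in the 90 PyMT cells of wild-type clusters. Lpl, the lipoprotein lipase gene, was at 10.7 and 0.430 CPM, a log2 ratio of -4.64 (-5.40 to -3.96). The hyaluronan synthase gene Has2 was at 4.65 and 0.271 CPM. Fmnl2, Dmwd and Stk39 had log2 ratios of -3.63, -4.08 and -2.84. Tmem45a2, Nat8l, Nrp1, Akap11, BC026585 and Rasl11b completed the 12 lowest genes, with log2 ratios between -3.02 and -2.67.

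**Figure D2:**
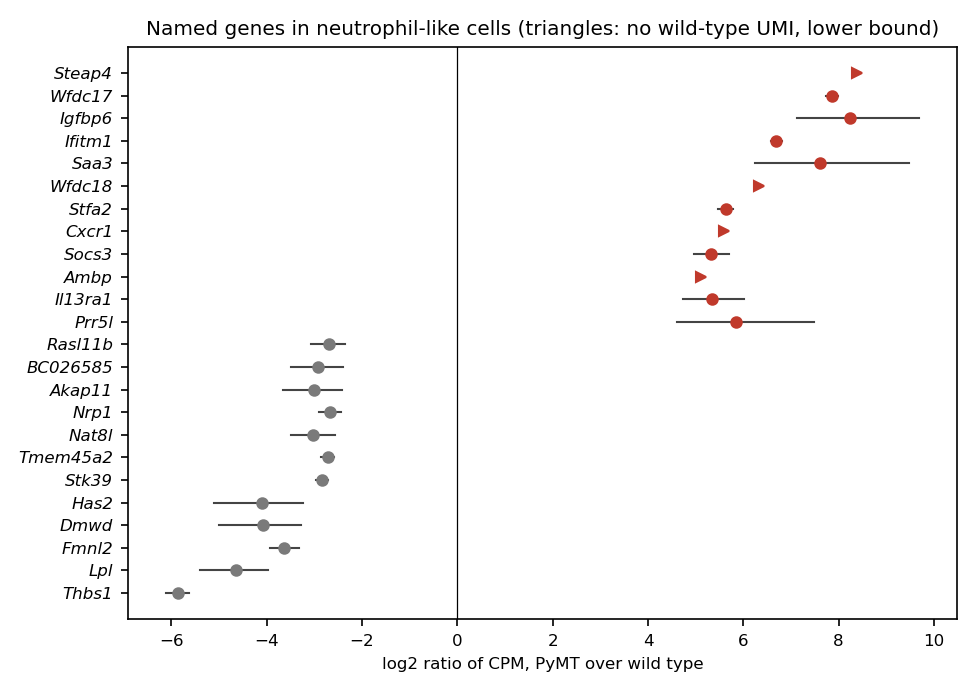
Log2 ratio of CPM (PyMT over wild type) of the 12 highest and 12 lowest genes in neutrophil-like cells, with counting intervals as lines. Triangles mark genes with 0 wild-type UMIs, drawn at the lower bound. Wfdc17 lies at 7.86 and Thbs1 at -5.87.

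Gene lists fixed before the data were examined were compared in the same cells. Of 29 interferon response genes, 24 were at least 1.5-fold higher in PyMT and 0 were lower, with a median log2 ratio of 1.66 that lay above all 10000 random lists matched on expression. Rtp4 was at 3.27 and 54.4 CPM, a log2 ratio of 4.06 (3.70 to 4.44). Of 16 genes that accounts of this study link to suppressive cells, 13 were higher and 1 was lower, with a median of 1.63, also above all random lists. Those genes were chosen on these samples, so their direction is not independent evidence. Among them Il1b, an inflammatory cytokine gene, was at 22.3 and 478 CPM, a log2 ratio of 4.42 (4.28 to 4.56), and 163 of its 437 wild-type UMIs lay in the 55 cells of PyMT clusters. Arg2, which encodes an arginase, was at 13.9 and 81.2 CPM, a log2 ratio of 2.55 (2.37 to 2.73). Pla2g7 had a log2 ratio of 3.40, while Il1rn, the interleukin 1 receptor antagonist gene, had one of -0.82. Of 9 primary granule genes, 8 were higher, among them Srgn at 36.5 and 387 CPM and Prtn3 at 3.83 and 34.2 CPM. Of 20 late maturation genes, 11 were higher and 2 lower, with a median of 0.75. Of 15 secondary granule genes, 0 were higher and 3 lower, with a median of -0.28 (percentile 0.405). Camp, the cathelicidin gene of that list, was at 71861 CPM in wild type and 32393 in PyMT.

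The clusters that hold these cells differed between the libraries, as described below, and 2 PyMT clusters low in Camp carried much of the difference. Without those clusters, an alternative chosen after the data were seen, 11 of the 16 genes linked to suppressive cells were higher and the median was 0.71. The interferon median was then 1.24 with 22 of 27 genes higher, and the late maturation median was 0.28 with 5 of 20 genes higher. The secondary granule median, at -0.18, then lay within the random range, as did those of chemokine and adhesion receptors, MHC class II and hypoxia, at 0.20, 0.20 and 0.03. The immediate-early median lay below it at -0.26 and that of ribosomal proteins above it at 0.14. The inflammatory median was -0.15 with 3 of 20 genes higher and 8 lower, and the cell cycle median 0.41 with 14 of 34 higher and 1 lower. Small differences depend on the scaling, since the median of all 8784 genes lay at -0.18 in CPM and moved by 0.19 with a trimmed mean of M-values.

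The other lists were compared in the same way. The alarmin and antimicrobial list had 11 of 22 members higher and a median of 0.57. Lysosome genes had a median of 0.40, with 7 of 21 higher. The medians were 0.38 for chemokine and adhesion receptors, 0.36 for granulopoiesis transcription factors, 0.36 for MHC class II, 0.34 for glycolysis and 0.24 for hypoxia. They were 0.20 for endoplasmic reticulum stress and 0.20 for the cell cycle, where 7 of 34 genes were higher and 2 lower, although that median was -2.45 with each library clustered on its own. Nuclear genes of oxidative phosphorylation had a median of -0.34, with 7 of 31 lower. Medians within the range of random lists were 0.10 for NADPH oxidase and ROS defence, 0.07 for inflammatory cytokines and NF-kB, 0.06 for immediate-early genes and 0.04 for lipid handling. Classical suppressor genes lay there as well, with a median of 0.01, 3 members higher and 3 lower. MHC class I, mitochondrially encoded genes and ribosomal protein genes also lay within that range, at -0.13, -0.15 and 0.03, as did the sorting panel at -0.06. Medians between -0.15 and 0.06 changed sign with at least 1 other scaling and are given no direction. Arg1 was seen in 0 of 5240 PyMT neutrophil-like cells, with an exact interval for the share of cells with a UMI that reaches 0.07%. It had 0 UMIs in monocyte-like, B cell-like and T cell-like cells of both libraries too, so none of these classes shows that it could be captured. No mammary epithelium gene reached 50 UMIs in neutrophil-like cells, and of the sex-linked list Xist had a log2 ratio of -0.75.

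**Figure D3:**
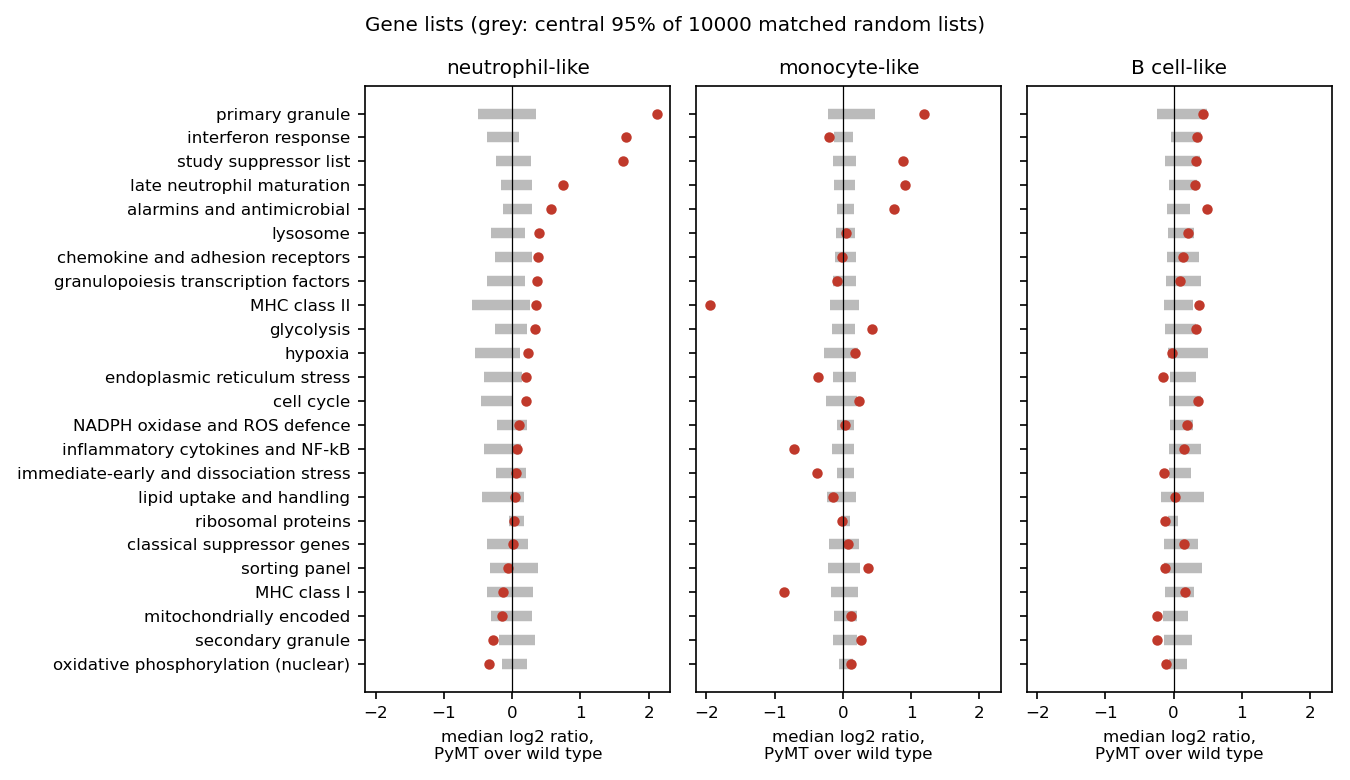
Median log2 ratio of CPM (PyMT over wild type) of each gene list (red points) in neutrophil-like, monocyte-like and B cell-like cells, over the central 95% of medians of 10000 random lists matched on expression (grey bars). In neutrophil-like cells the interferon response list lies at 1.66, and in monocyte-like cells MHC class II lies at -1.95.

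Because the antibody panel included CD84 and JAML, the genes of that panel were examined in neutrophil-like cells. Cd84 (ENSMUSG00000038147, chromosome 1, 171839697 to 171890718 on GRCm38) was at 41.8 CPM in wild type and 102 in PyMT, a log2 ratio of 1.29 (1.18 to 1.40). Amica1, the files' name for the JAML gene (ENSMUSG00000048534, chromosome 9, 45079183 to 45108534), was at 8.85 CPM (7.58 to 10.3) and 44.3 CPM (42.4 to 46.3), a log2 ratio of 2.33. Without the PyMT clusters low in Camp these log2 ratios were 0.23 for Cd84, under the 1.5-fold rule, and 0.65 for Amica1. At least 1 UMI of Cd84 was found in 20.9% of wild-type and 47.2% of PyMT neutrophil-like cells, and in 4.84% and 13.2% after each cell was thinned to 1000 UMIs. For Amica1 these shares were 4.44% and 23.6%, and 1.05% and 7.08% after thinning. Neither gene was particular to neutrophil-like cells. In monocyte-like cells the Amica1 shares were higher, at 34.8% and 56.4%, and 9.06% and 13.9% after thinning. Cd84 was seen in 21.4% and 40.4% of them, and in 4.71% and 7.67% after thinning. T cell-like cells, before thinning, had shares of 28.2% and 42.3% for Cd84 and of 10.3% and 13.7% for Amica1. B cell-like cells, at the lower depths given above, had shares of 22.1% and 27.2% for Cd84 and of 8.77% and 7.54% for Amica1. The wild-type neutrophil-like shares of both genes lay below these. In B cell-like cells Cd84 was at 64.7 and 85.6 CPM and Amica1 at 22.9 and 20.5 CPM, above the wild-type neutrophil-like levels. Those cells may thus express both genes and are no sure measure of free RNA. The shares on their own do not separate expression from free RNA. The levels differed between wild-type clusters, however, with Amica1 at 11.2 CPM (9.38 to 13.3) in cluster 1 and 1.83 CPM (0.95 to 3.20) in cluster 6, and Cd84 at 56.8 and 17.4 CPM. Of the genes of the sorting antigens, Itgam, which encodes CD11b, had a log2 ratio of -0.67 and Ly6g one of -0.59, and with median-of-ratios scaling both were under the 1.5-fold rule, at -0.49 and -0.41. Fcgr3 had a log2 ratio of 0.93. Ly6c2, Ly6c1, Ptprc and Fcgr2b had log2 ratios of -0.06, 0.05, -0.11 and -0.14, each of which changed sign with at least 1 other scaling.

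To see which neutrophil-like cells carried the genes linked to suppressive cells, clusters made without those genes were compared. Of 8485 neutrophil-like cells, 97.1% lay in clusters with at least 90% of cells from 1 library. Clusters 1 and 6 held 2171 and 953 wild-type cells, and clusters 3, 5, 7, 9 and 10 held 1286, 1223, 963, 655 and 588 PyMT cells. A cluster held almost wholly by 1 library may be that library rather than a cell type. Within the PyMT library, cluster 3 stood apart, with 15 of 16 genes linked to suppressive cells at least 1.5-fold higher than in the other 3954 PyMT neutrophil-like cells and a median log2 ratio of 2.42. Cluster 9, the other cluster low in Camp, had 11 of 16 higher and a median of 0.86, also above all random lists. These genes also differed between clusters within the wild-type library. There the 2171 cells of cluster 1 had 11 of 16 higher than the other 1074 neutrophil-like cells, with a median of 1.11, above all random lists. The genes were chosen on these samples, so none of these clusters is independent evidence of suppressive cells. Wfdc17 was at 29252 CPM in cluster 3, 11624 in cluster 9 and 745 in cluster 5, against 8.43 in the wild-type cells of cluster 1. Cd84 was at 412 CPM in cluster 3 (394 to 430) and 27.5 in cluster 5, and Amica1 was at 250.1 and 6.18 CPM. Other lists left out of the clustering also differed in cluster 3, with medians of 1.70 for inflammatory, 1.47 for immediate-early, 1.21 for interferon and -2.09 for cell cycle genes. Immediate-early genes rise in stressed cells, and 20 of 22 were higher there. Camp and late maturation genes took part in the clustering, so their levels describe the cluster and are not results. Cells of cluster 3 were shallow, with a median of 3333 UMIs.

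**Figure D4:**
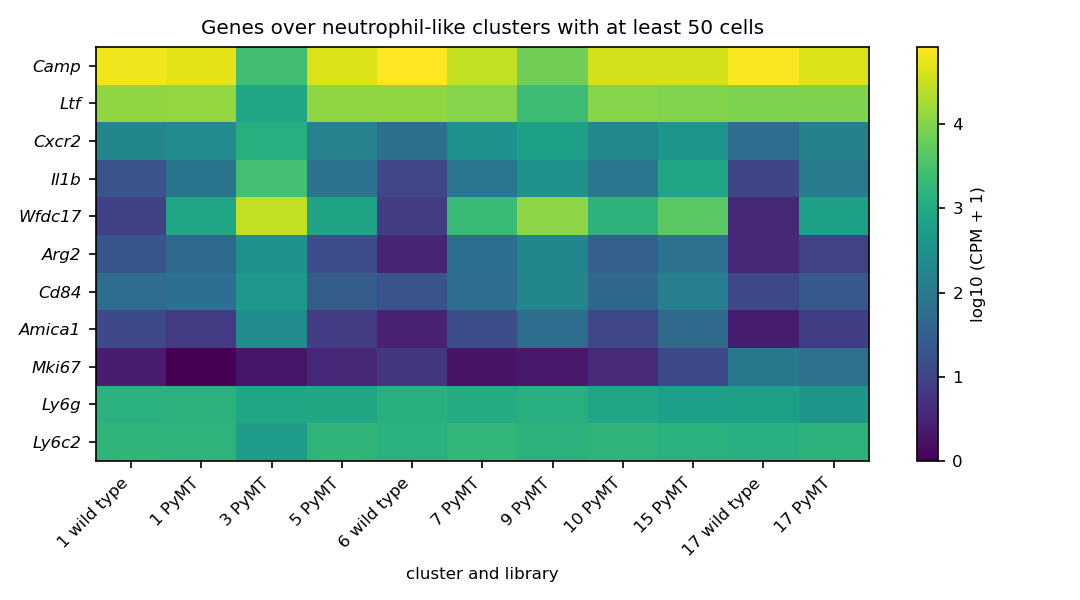
Level of 11 genes, as log10 of CPM plus 1, in each neutrophil-like cluster and library with at least 50 cells. Il1b, Wfdc17, Cd84 and Amica1 are highest in cluster 3 of the PyMT library, where Camp is lowest.

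The same comparison was made in 552 wild-type and 1630 PyMT monocyte-like cells. Genes of MHC class II, which present antigen to helper T cells, were lower in PyMT, with 10 of 10 at least 1.5-fold lower and a median log2 ratio of -1.95, below all 10000 random lists. That list also holds the costimulatory genes Cd86, Cd80 and Cd40. H2-Ab1 was at 2333 CPM in wild type and 178 in PyMT, a log2 ratio of -3.71 (-3.78 to -3.64), and Cd74, the invariant chain gene, was at 7767 and 838 CPM. H2-Aa had a log2 ratio of -3.56. The wild-type cells were not alike, since of 171 with Ly6c2 and Ccr2 UMIs and none of Ace, Treml4, Cd209a and Flt3, 29.8% had an MHC class II level above the central 95% of such PyMT cells. MHC class I genes were lower for 9 of 11 members with a median of -0.87, among them H2-K1 at 1366 and 561 CPM. Inflammatory and NF-kB genes were lower for 14 of 20 and higher for 2, with a median of -0.71, while the log2 ratio of Il1b was 1.77 with cluster 14, which carries neutrophil transcripts, and 0.43 without it. The interferon list had 4 of 29 genes higher and 8 lower, with a median of -0.20. Cxcl10, an interferon-induced chemokine gene, Cd209a, a marker of dendritic and monocyte-derived cells, and the survival gene Bcl2a1b had log2 ratios of -4.84, -4.29 and -3.63. The highest genes were Ifitm1, Prok2, Igfbp6, BC100530 and Stfa2, with log2 ratios of 5.34, 5.67, 5.17, 4.64 and 5.06, and BC117090 with 0 wild-type UMIs and a log2 ratio of at least 4.38. Many of those are neutrophil genes, and cluster 14 held 3 wild-type and 283 PyMT cells. Without it, an alternative chosen after the data were seen, the inflammatory list had 0 genes higher and 15 lower, and the late maturation median in monocyte-like cells was 0.12 in place of 0.92, while the MHC class II median was -1.93. The secondary granule median was then 0.02, and those of the genes linked to suppressive cells and of alarmins 0.41 and 0.39. Ifitm1, BC100530 and Stfa2 were also among the highest genes of B cell-like cells, and free neutrophil RNA was not weighed in monocyte-like cells.

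The other lists in monocyte-like cells went both ways. Medians above the random range were 1.19 for primary granule genes, 0.87 for the genes linked to suppressive cells, 0.75 for alarmins, 0.43 for glycolysis, 0.36 for the sorting panel, 0.27 for secondary granule genes and 0.23 for the cell cycle. Without cluster 14 the secondary granule and cell cycle medians lay within the random range, the latter at 0.145. With clusters made on the list genes the secondary granule median was -0.18. Immediate-early and endoplasmic reticulum stress genes lay below that range, at -0.38 and -0.36. Among the former Hspa1a, a heat shock gene, was at 1446 CPM in wild type and 493 in PyMT.

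In B cell-like cells (285 wild-type and 994 PyMT), the highest genes were Wfdc17, Ifitm1, BC100530, Stfa2, Hbb-bs and Stfa2l1, which B cells are not known to express at such levels. Wfdc17 was at 14.7 and 558 CPM, and Ifitm1 at 20.5 and 378 CPM. S100a8, a neutrophil gene, was at 8501 CPM in wild-type and 8447 CPM in PyMT B cell-like cells. Jchain, the immunoglobulin joining chain gene of plasma cells, was at 255 CPM in wild type and 2.07 in PyMT, but its 311 wild-type UMIs came from 4 of 285 cells. Hspa1b, Camp, Hsp90b1, Rgs10 and Lepr were the other lowest genes, with log2 ratios of -1.72, -1.06, -1.08, -1.20 and -1.46. Camp, a secondary granule gene of neutrophils, was at 2414 CPM in wild type and 1160 in PyMT. It was also lower in PyMT neutrophil-like cells, and whether free neutrophil RNA gives its difference here was not tested. MHC class II had a median of 0.37, with 1 of 10 genes higher and 0 lower, while the median of all 6608 genes lay at 0.15 and moved by -0.15 with the median of ratios. Secondary granule genes stood at 3.72% of their neutrophil-like level in these PyMT cells.

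Over the whole libraries, before any class was drawn, the protease genes Prss34 and Mcpt8 of basophils had 0 wild-type UMIs and 1008 and 460 PyMT UMIs, of which 949 came from 3 cells and 380 from 1 cell of the progenitor-like class. Ifitm1, Steap4, Igfbp6 and Stfa2 had log2 ratios of 6.73, 6.95, 6.30 and 5.85. The haemoglobin genes Hbb-bs and Hbb-bt had log2 ratios of 6.28 and 6.46, and 45892 of the 49779 PyMT UMIs of Hbb-bs came from 27 erythroid-like cells, a class with 1 cell in wild type. Thbs1 (-4.90), Nkd1 (-5.40), Ces1d (-5.14), Lpl (-3.99), Fmnl2 (-3.65), Has2 (-4.04), Dmwd (-3.50) and Clec4b2 (-3.45) were lowest. Cell cycle genes were lower in PyMT for 29 of 38 members, with a median log2 ratio of -0.78. Whether this follows the smaller PyMT shares of progenitor-like and mixed cells was not tested. The former difference reversed with each library clustered on its own.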

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

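The tests of mixing between libraries, of separation outside the clusters low in Camp, of monocyte subsets and of subset cells that pass their gate, of neutrophil RNA in B cell-like cells and of B cell RNA in monocyte-like cells were chosen after their results, or part of them, had been seen, and leaving out clusters low in Camp was added after the data were seen, before its own result was known.

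The medians of some gene lists had opposite signs in different classes of the same libraries, although few members passed 1.5-fold in some of them. The MHC class II median log2 ratio was -1.95 in monocyte-like cells, 0.37 in B cell-like cells and 0.36 in neutrophil-like cells. In B cell-like cells 1 of 10 members was higher. In neutrophil-like cells 2 were higher, Cd86 and Cd40, and 1 was lower, Cd80. Those are costimulatory genes that the list holds beside genes of MHC class II itself. Without clusters low in Camp the neutrophil-like median lay within the random range at 0.20. The interferon response median was 1.66 in neutrophil-like and -0.20 in monocyte-like cells, where 8 of 29 members were lower and 4 higher and the median fell within the random range at -0.12 when thinned and -0.077 over members with at least 200 UMIs. With 1 library per group, neither difference between classes was tested.

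The neutrophil-like cells of the libraries fell in separate clusters, and in equal draws of 285 cells per library, 4.40% of the nearest neighbours of neutrophil-like cells came from the other library, against 13.2% for monocyte-like and 33.3% for B cell-like cells. A technical difference that shifts every cell of a library alike was taken to mix both types about equally little. The share was 7.55 times as high in B cell-like cells (6.18 to 10.1 over 10 draws). Median depth was close between libraries in B cell-like cells (3643 and 3349 UMIs) but not in neutrophil-like cells (5227 and 8087.5 UMIs). The classes are thus not alike enough for the ratio to decide the question. Of 179 genes at least 4-fold different, 98.3% stayed at least 2-fold apart in cells of 5000 to 6000 UMIs. CPM already divides by depth, and those cells were not clustered anew. The 179 genes were chosen as different in the same cells, of which the 727 wild-type and 320 PyMT matched cells are a part. PyMT clusters also differed in depth, with medians of 3333 UMIs in cluster 3, 6170 in cluster 9 and 10817 in cluster 5. The matched cells may therefore hold another mix of clusters. Those gene differences were still seen at that depth, but the share is no independent check. Whether deeper PyMT cells add to the separation was not tested. Clusters low in Camp did not hold the whole separation, since 96.3% of the 6540 cells outside them lay in clusters of 1 library. Those cells were not clustered anew, and their stage was not matched. Camp was at 46727 CPM in PyMT cluster 5 and 28853 in PyMT cluster 7, against 65987 and 83152 in wild-type cells of clusters 1 and 6. A difference in stage thus stays open as a cause of the separation. A larger share of late-stage cells low in Camp may account for part of the median of the genes linked to suppressive cells. That median was 0.71 without those clusters (0.49 to 1.34 over resampled members) and 1.63 with them. Tumour, strain background, animal pool, depth and any other effect of the library remain confounded.

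Lower MHC class II in PyMT monocyte-like cells was weighed against free B cell RNA which, scaled by Cd79a, would give 1.55% (1.21 to 1.96%) of the MHC class II UMIs of wild-type monocyte-like cells, too little to account for the difference. Another mix of subsets stays open. It was examined in cells with Ly6c2 and Ccr2 UMIs and none of Ace, Treml4, Cd209a and Flt3 (171 wild-type and 914 PyMT cells). Their MHC class II median was -1.25 (-4.18 to -0.86 over resampled list members). The log2 ratio of the median level per cell was -1.40 (-1.79 to -1.06 over resampled cells). Neither range is a replicate check. The cells so chosen were shallower in wild type (5191 against 7257.5 UMIs), so subset cells whose markers were not captured may have stayed among them. Of the wild-type cells, 29.8% lay above the central 95% of the PyMT cells, enough to move a median. Tumour and strain background are confounded here as well, and 9 of 22 immediate-early and dissociation stress genes were at least 1.5-fold lower in PyMT monocyte-like cells, with 1 higher. A lower MHC class II level in each monocyte of tumour-bearing mice is therefore only a candidate explanation beside the mix of subsets, strain and pool.

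Neutrophil genes led the higher genes of PyMT B cell-like cells. If free neutrophil RNA is the source, it should bring them in proportion, and secondary granule genes in these cells stood at 3.72% of their neutrophil-like level. The 5 genes had a median of 1.47 times the level this predicts, with BC100530 at 1.08 and Stfa2 at 1.04 but Wfdc17 at 2.62 and Ifitm1 at 3.33. Free RNA may thus account for BC100530 and Stfa2, whereas for the 5 genes together the resampled range of 1.04 to 3.33 leaves it undecided. Monocyte-like cells also carry Wfdc17 and Ifitm1 and were not part of the prediction.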

How the results depend on the processing

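Leaving out clusters low in Camp or with neutrophil transcripts was chosen after the data were seen; the other alternatives were planned. In neutrophil-like cells the median log2 ratio of the genes linked to suppressive cells ranged from 0.71 to 2.03 over the alternatives, that of interferon genes from 1.24 to 2.02 and that of late maturation genes from 0.28 to 0.94, each above the random range throughout. In monocyte-like cells MHC class II ranged from -2.03 to -1.21 and MHC class I from -0.90 to -0.65, below it throughout. Over all alternatives, list medians stayed inside or outside the random range in 978 comparisons, with a change of sign in 64 of them, passed it in 57 (7 with a change of sign), fell inside it in 37 and reversed from outside it in 6. Genes stayed on their side of the rule for a difference in 3876 comparisons, with a change of sign in 39, passed it in 81 (3 with a change of sign), fell short of it in 177 and reversed in 22.

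With each library clustered on its own, the PyMT minus wild-type share was -6.69 percentage points for neutrophil-like cells (-1.83 in the main comparison), 5.72 for monocyte-like cells (7.76) and 0.93 for myeloid progenitor-like cells, where it reversed (-3.76). At Leiden resolution 0.5 it was 4.79 for monocyte-like and -4.96 for mixed cells. With doublets left out it was 8.91 for B cell-like and -14.1 for mixed cells. The share of neutrophil-like cells in clusters of 1 library was 100% with doublets left out, 94.1% at resolution 0.5 and 92.6% with the list genes; clustering each library on its own cannot give this value.

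The inflammatory median in neutrophil-like cells passed the random range at 0.40 with equal weight per cell, 0.41 when thinned, 0.14 with each library on its own and 0.26 over members with at least 200 UMIs, but was -0.15, within it, without low-Camp clusters, and the secondary granule median fell inside it at -0.18 without low-Camp clusters. The cell cycle median there reversed to -2.45 with each library on its own, with 2810417H13Rik at -2.5, Ccna2 at -2.02 and Ccnb1 at -0.46. In monocyte-like cells the secondary granule median reversed to -0.001 with doublets left out and -0.18 with the list genes, where Elane was at -0.12 and Fcnb at -0.34. The interferon median there was -0.12 when thinned and -0.077 over members with at least 200 UMIs, both inside the random range. When thinned, Cdc20 reversed to -0.34, Mcm3 to 0.14 and Acsl4 to 0.023 in monocyte-like cells. Mcm3 was also at 0.062 with doublets left out, 0.26 at resolution 0.5, 0.20 with each library on its own and 0.04 with the list genes.

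In thinned B cell-like cells the secondary granule median reversed to 0.086 and the endoplasmic reticulum stress median to 0.024, with Rrm2 at -1.22, Top2a at -1.06, Mcm6 at -0.22 and Irf4 at 0.005. With doublets left out, their immediate-early median was 0.22, Mmp9 was at 0.051 and Tnfaip2 at 0.18. Rrm2 was at -0.48 with equal weight per cell, and with each library on its own Il1b was at -0.054, Mcm6 at -0.052 and Fcgr3 at -0.16. The causes of these changes were not tested. With 1 library per group no replicate could be left out. Depth limits the B cell-like class most, with 285 wild-type cells at a median of 3643 UMIs.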

Other observations

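The values here were chosen after they were seen. Basophil protease genes came from very few cells: of the Prss34 UMIs of the PyMT library, 949 were in 3 of 118 progenitor-like cells, and 380 Mcpt8 UMIs were in 1 cell. Neutrophil-like PyMT cells held 41 Prss34 UMIs in 41 cells, 1 UMI each. Jchain was as concentrated, with 311 UMIs in 4 wild-type B cell-like cells and 562 in 8 wild-type mixed cells.

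Cd3d, a gene of the T cell receptor complex, was found in 2855 of 3245 wild-type and 3547 of 5240 PyMT neutrophil-like cells, at 452 and 233 CPM. Cd3e, another gene of that complex, was at 0.102 and 0.430 CPM in the same cells. In T cell-like cells Cd3d was at 706 and 754 CPM and Cd3e at 263 and 357 CPM. In B cell-like cells Cd3d was at 26.2 and 13.2 CPM.

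Transcripts of the keratin genes Krt8 and Krt19, which mammary epithelium expresses, were seen in PyMT cells of several classes, almost always at 1 UMI per cell. Krt8 had 25 UMIs in 25 neutrophil-like and 7 in 7 monocyte-like PyMT cells. Krt19 had 56 UMIs in the PyMT library and 0 in wild type, among them 29 in 29 neutrophil-like, 12 in 12 monocyte-like and 6 in 5 mixed cells. No cluster was led by keratins.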
